A study of Mus musculus with 8 samples.

How the data were processed

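Total RNA from sorted haematopoietic stem cells of mouse fetal liver was measured on 8 Affymetrix mouse expression arrays, 4 from wild-type and 4 from Crebbp+/- embryos on a C57BL/6 background. Per the labels, cells were lineage-negative, AA4.1-positive and strongly c-Kit-positive, each preparation combined 15 embryos, and 12 ng of total RNA was amplified and turned into biotin-labelled cDNA. The labels give the age as 14.5 days post coitum in their description and as 14 in their characteristics. The titles number 2 samples in each genotype and 2 replicate arrays of each sample. Nothing in the labels says whether the 2 arrays came from separate cells, so they were treated as repeat measurements and averaged, which left n = 2 samples per genotype. Whether the numbered samples came from separate litters is not stated either, so limma p-values of single probe sets measure the spread between these preparations.

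The deposited values are on the log2 scale and were made with GCRMA, a background correction and normalization for this type of array, per the submitters' processing notes. Its version and settings are not given in the sources used here. The table held 45101 probe sets, and the median over all probe sets lay between 2.65 and 2.70 on every array, so most probe sets sat close to the background that the normalization assigns. No scanner files were used here. The precision is limited by the number of arrays.

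Gene names came from the platform annotation supplied with the data and were updated through gene identifiers to the GRCm38.p6 gene table, which was used for names and for the order of genes only. After removal of 64 control probe sets, 34945 of 45037 probe sets carried 1 gene symbol, 932 carried several and 9160 had none listed. Gene identifiers of 34741 probe sets matched, and no symbol changed. A probe set with no listed symbol is unnamed here, which does not mean that it measures no gene, and a probe set with several symbols named none.

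The 22518 probe sets whose mean exceeded the median of 2.72 were tested. Of these, 19054 had 1 symbol, covering 10600 genes, 562 had several and 2902 had none. Log2 values averaged per sample were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The fit had 2 residual and 4.75 total degrees of freedom. With 2 samples against 2, an exact two-sided permutation test cannot go below 0.33, so no such test was used. A gene's value in the gene lists was that of its probe set with the highest mean, whereas the 12 genes named in each direction were chosen by single probe sets. Positive differences are higher in Crebbp+/-.

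Of 49 gene lists, 45 had at least 5 measured genes and were tested with limma's camera at a preset inter-gene correlation of 0.01. Camera compares a list's genes with other genes, so at this preset its p-values do not measure the spread between samples. The same lists were tested with an estimated correlation and with fry, which asks whether a list's genes move on balance in the same direction without comparing them with other genes. Members were also adjusted over the list alone. The share of differing genes among those nearest Crebbp was to be compared with all other genes by Fisher's exact test, two-sided, which tells nothing where no gene passes and is given for unadjusted p only. The genes named were Crebbp and its paralog Ep300, 12 genes in each direction, and members of each list. Among genes past the test, the 12 were those with the largest difference and with all 4 arrays of a genotype above all 4 of the other. Where fewer passed, the places went to the lowest unadjusted p among such separated probe sets. In each list, up to 4 passing members were named, or else the 2 with the lowest p, and in lists of other cell types, cell handling and sex also the 2 with the highest mean. Groups, lists, tests, this rule and most alternatives were fixed before the data were examined.

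Both procedures were tested on simulated data. With 200 of 22518 probe sets shifted by 1 or 2 log2 units and the spread seen between these samples, limma recovered 0% in each case, and with a shift of 3 it recovered 57.5%. With a smaller spread it recovered 85.5% of shifts of 2. A list of 30 genes shifted by 0.3 was called by camera in 100% of 20 runs, with 1 false call among 800 other lists. These list simulations held no shared variation between genes of a list.

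Alternatives covered the unit of replication, the sample number as a block, the filter, added normalizations, a floor, the variance model, thresholds, the choice of probe set and the omission of each sample and each array. Further fits, with a 2-level block on 8 arrays or with a covariate for RNA integrity, were added after the data had been seen, as were lists without shared genes and a count of neighbouring genes by unadjusted p.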

Results

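The data compare gene expression in fetal liver haematopoietic stem cells of embryos that carry 1 mutant copy of Crebbp with that of wild-type embryos. Crebbp encodes CBP, a histone acetyltransferase and transcriptional coactivator, and the series title links its loss to DNA repair defects and to MDS, which stands for myelodysplastic syndrome, a clonal disorder of blood formation. Each genotype was represented by 2 numbered samples of 15 combined embryos, and each sample by 2 arrays. Values are GCRMA log2 signals, given as means of the 2 samples with n = 2 per genotype, and differences are Crebbp+/- minus wild type with the standard error of the limma fit.

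Kit and Mpo were expressed in both genotypes, and of 44 listed stem cell genes 38 had a mean signal above the filter of 2.72. Kit, the stem cell factor receptor, had a mean log2 signal of 9.20 ± 0.22 (SD, n = 2) in wild type and 9.33 ± 0.01 in Crebbp+/-, and Mpo, a granule enzyme of myeloid progenitors, had 12.88 ± 0.02 and 12.92 ± 0.12. The 2 arrays of a sample correlated across probe sets with a median r of 0.982. Arrays of different samples of the same genotype correlated with a median r of 0.968. Arrays of different genotypes with the same sample number correlated at 0.974, above the value within a genotype, and those with different numbers at 0.962. Genes are not independent replicates in these correlations.

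The sample number went with the Gapdh 5' minus 3' signal in both genotypes, and with liver transcripts in wild type alone. The 5' signal of the Gapdh control, which falls behind the 3' signal as RNA degrades, lay below it by log2 differences of -1.22 and -2.59 in wild-type samples 1 and 2, and of -0.89 and -1.88 in Crebbp+/- samples 1 and 2. The genotypes overlapped in this measure, which averaged 0.52 higher in Crebbp+/- (0.33 and 0.71 within the samples numbered 1 and 2), less than the SD of 0.97 in wild type and 0.70 in Crebbp+/- (n = 2). Among controls other than mRNA, probe sets for 18S ribosomal RNA differed between genotypes by -0.53, -0.78 and -1.16, that for the B1 repeat by -0.41 and that for the B2 repeat by -0.02. Alb, encoding the hepatocyte product albumin, had a log2 signal of 2.43 in wild-type sample 1 and 7.06 in wild-type sample 2, against 5.85 and 5.74 in the Crebbp+/- samples. Afp, encoding alpha-fetoprotein, ran from 3.68 to 8.50 in wild type and from 6.71 to 7.08 in Crebbp+/-. For this reason, differences are also given within the samples numbered 1 and within those numbered 2.

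**Figure D1:**
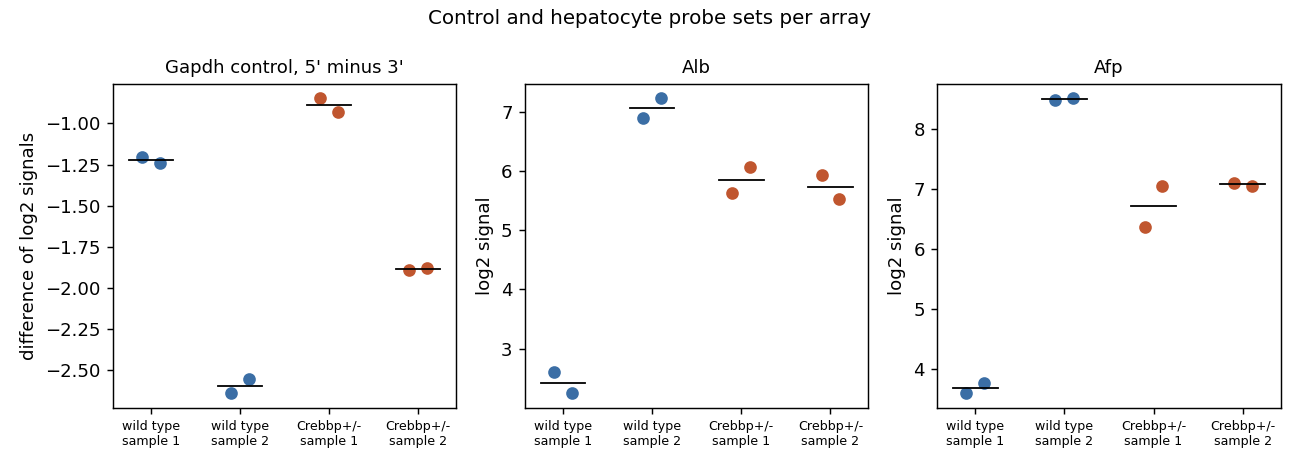
Log2 signal of each array (points) for the Gapdh control, as 5' minus 3', and for the hepatocyte genes Alb and Afp, with the mean of each sample as a line, by genotype and sample number. The Gapdh difference was lower in the samples numbered 2 of both genotypes, at -2.59 and -1.88, and Alb was lowest in wild-type sample 1, at 2.43.

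Crebbp transcript was detected in both genotypes, with no difference past the test. The brightest of its 4 probe sets had a log2 signal of 11.74 ± 0.46 (SD, n = 2) in wild type and 11.81 ± 0.21 in Crebbp+/-, a difference of 0.07 (SE 0.26, 95% confidence interval -0.62 to 0.75, limma adjusted p = 0.999). The others differed by 0.01 (SE 0.49, interval -1.26 to 1.29), -0.42 (SE 0.29, interval -1.19 to 0.34) and -0.35 (SE 0.24, interval -0.98 to 0.28), and none passed the test. Within the samples numbered 1 and 2 the brightest probe set differed by -0.11 and 0.25 and the next by -0.16 and 0.18, while the dimmer ones were lower in both, by -0.69 and -0.16 and by -0.47 and -0.23. Ep300, encoding the paralogous acetyltransferase, differed by 0.24 (SE 0.18, adjusted p = 0.991). The part of Crebbp removed by the mutant allele is not in the labels, and a probe set outside it does not check the genotype.

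No probe set and no gene passed the test between genotypes. The lowest adjusted p in limma was 0.991. An unadjusted p under 0.05 was found for 1089 of 22518 probe sets, where 1126 would be expected by chance with independent samples. Same-numbered samples deviated alike across probe sets (correlation 0.55), so 1126 may not be the chance level here. Grouping the samples across both genotype and number gave 154 such probe sets. Of the 1089, 276 were higher and 813 lower in Crebbp+/-. Probe sets with no listed gene name, 2902 of those tested, supplied 394 of the lower and 17 of the higher ones. Those with 1 name supplied 411 and 250. With all 8 arrays taken as independent, 1 probe set was called lower. Both samples of a genotype lay above both of the other for 6986 probe sets, or 31.0%, where chance gives 33.3% with independent samples. All 4 arrays of a genotype lay above all 4 of the other for 1571, or 6.98%, where chance would give 2.86% with independent arrays and up to 33.3% with arrays that repeat their sample. In simulated data with this spread, 0% of changes of 2 log2 units were recovered, and with a smaller spread 85.5%. The spread used includes the difference between sample numbers. The absence of calls therefore does not exclude differences of that size.

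The genes below had the lowest unadjusted p in each direction, with fully separated arrays, and none passed adjustment. Among those higher in Crebbp+/- were Cpa3, encoding a mast cell carboxypeptidase, at 2.18 (SE 0.29), and Sema3d, encoding a secreted semaphorin, at 2.56 (SE 0.53). Cpa3 differed by 2.35 within the samples numbered 1 and by 2.00 within those numbered 2, and Sema3d by 2.37 and 2.74. Bcat1, encoding cytosolic branched-chain aminotransferase, differed by 1.55 (SE 0.22), and Gli3, a transcription factor of the hedgehog pathway, by 1.21 (SE 0.26) with its second probe set at 1.07. Fech, encoding the enzyme that inserts iron into haem, differed by 1.23 (SE 0.27), with its other probe sets at 1.08 and -0.06. Shisa2 differed by 1.18 (SE 0.26) and by 0.96 at its other probe set. The remaining genes of this direction were Dnajc6 at 1.45, Gdpd1 at 1.18, Eif5a2 at 1.11, Spaca9 at 1.09, Nrk at 1.05 and Jmjd4 at 0.88. Nrk and Jmjd4 had wild-type signals of 2.61 and 2.59, below the filter of 2.72, so the size of these differences is uncertain, and the brightest probe set of Nrk differed by -0.06 (SE 0.59).

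Among the genes lower in Crebbp+/-, Tspan8, encoding a tetraspanin of the cell surface, was lower at all 4 of its probe sets, by log2 differences of -2.55 (SE 0.39), -1.77, -1.58 and -1.53. Within the samples numbered 1 and 2 the first of these differed by -3.06 and -2.03. Mir99ahg, the host transcript of a microRNA cluster, differed by -1.65 (SE 0.27) and by -0.99 at its second probe set. Gm20199, Disp1, Lonp2 and Ccny differed by -2.60, -2.47, -2.14 and -1.76, and Phxr4, Msi2, Birc6, Prr5l, Plpp1 and Rmdn1 by -1.47, -1.42, -1.36, -1.26, -1.13 and -1.11. Other probe sets of several of these genes did not follow. For Msi2, encoding an RNA-binding protein of haematopoietic stem cells, the brightest probe set differed by -0.10 (SE 0.20), and for Birc6 by -0.12 (SE 0.28). For Ccny the brightest differed by 0.41 (SE 0.18), and for Prr5l by 1.09 (SE 0.36). For Lonp2 and Rmdn1 the brightest differed by -0.20 (SE 0.30) and -0.22 (SE 0.47). Signals of Prr5l, Plpp1 and Rmdn1 in Crebbp+/- were 2.76, 2.70 and 2.54, at background, so the size of their differences is uncertain.

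**Figure D2:**
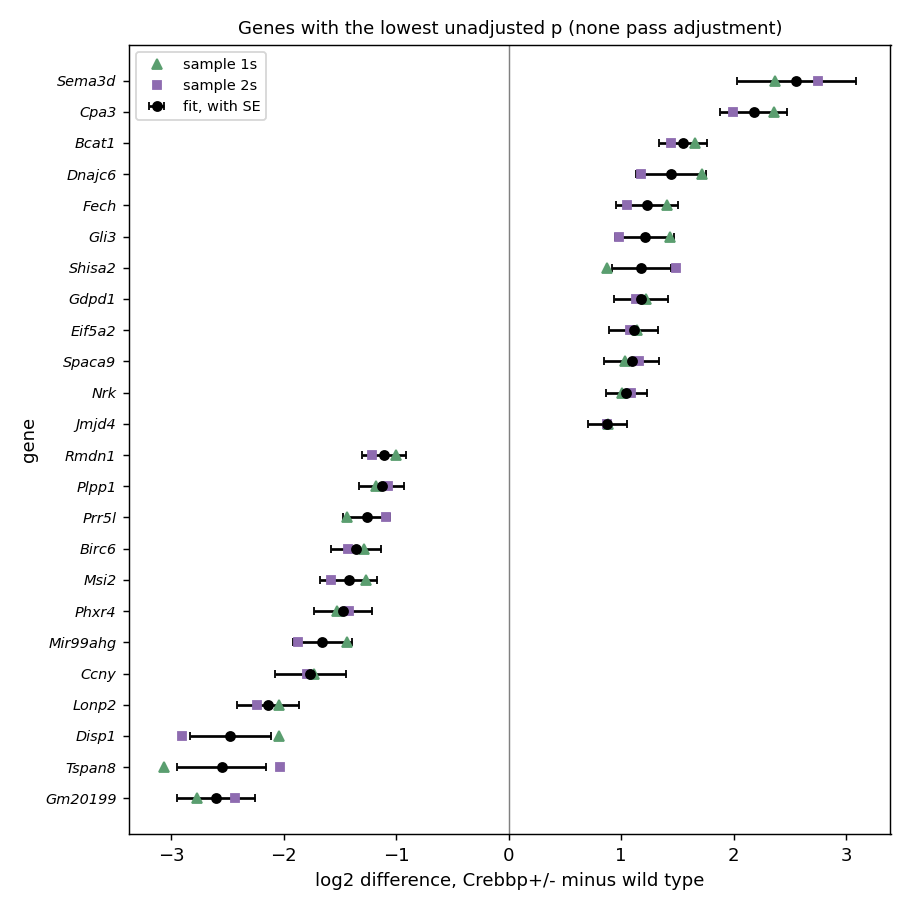
Log2 difference, Crebbp+/- minus wild type, of the 12 higher and 12 lower genes with the lowest unadjusted p and separated arrays. Circles give the fit with its SE (n = 2 samples per genotype), triangles the difference within the samples numbered 1 and squares that within the samples numbered 2. Values run from -2.60 for Gm20199 to 2.56 for Sema3d, and none passed adjustment.

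The series title names DNA repair, and 7 lists covered repair pathways and the damage checkpoint. None of the 7 stood apart from other genes, with camera adjusted p from 0.50 to 0.97. Their median differences were 0.13 for homologous recombination (24 genes), 0.12 for the damage checkpoint (23 genes), 0.08 for the Fanconi anaemia pathway (16 genes), 0.05 for nucleotide excision repair (24 genes), 0.04 for mismatch repair (15 genes), -0.01 for non-homologous end joining (10 genes) and -0.04 for base excision repair (19 genes). With 1 sample or array omitted, the medians ranged from 0.017 to 0.20 for recombination, from 0.012 to 0.16 for the checkpoint and from 0.021 to 0.12 for the Fanconi pathway, and those of the other 4 lists took both signs. For mismatch repair the camera statistic had the opposite sign to the median, and for base excision repair and end joining the median and the mean had opposite signs. No member passed the test over all genes or adjusted over the list alone. In the Fanconi list the members with the lowest p were Fancc, a component of the Fanconi core complex, at 0.88 (SE 0.29), and Faap24, its partner, at 0.62 (SE 0.29). In nucleotide excision repair, Gtf2h1, a subunit of transcription factor TFIIH, differed by 0.83 (SE 0.32) and Ddb2, a damage sensor, by -0.66 (SE 0.29). Lig4 and Xrcc5 of end joining differed by 0.77 (SE 0.45) and 0.26 (SE 0.21), and Rad51d and Slx4 of recombination by 0.50 (SE 0.30) and 0.52 (SE 0.34). Mutyh and Mbd4 differed by 0.52 (SE 0.33) and 0.28 (SE 0.25), Rfc3 and Rfc4 by 0.40 (SE 0.29) and -0.33 (SE 0.23), and Rad1 and Chek1 by 0.48 (SE 0.23) and -0.30 (SE 0.20). In a list of 21 textbook targets of p53, a transcription factor that responds to DNA damage, the median was 0.19 (camera adjusted p = 0.42). Eda2r, a member of that list, differed by 1.32 (SE 0.21) and passed adjusted over the list alone (adjusted p = 0.040), not over all genes. Its wild-type signal of 2.67 lay at background, so the size of its difference is uncertain. Pmaip1, a pro-apoptotic gene, differed by 0.97 (SE 0.29) and did not pass.

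Genes of lymphoid commitment were higher in Crebbp+/- as a group. Of 14 lymphoid priming genes 12 had a positive difference, with a median of 0.51 (camera adjusted p = 0.015), and of 7 B cell genes 6 did, with a median of 0.63 (camera adjusted p = 0.013). With an estimated correlation the adjusted p was 0.82 for both. The 2 lists share 5 genes, and the 9 lymphoid priming genes outside the B cell list had a median of 0.06 and were not called (adjusted p = 0.34, a test chosen after seeing the data). Their leading members were Ccr9, a chemokine receptor of thymus-seeding cells, at 1.43 (SE 0.33), Rag1, a recombinase of antigen receptor genes, at 0.87 (SE 0.29), and Vpreb1, part of the surrogate light chain, at 0.63 (SE 0.27). Outside the naming rule, Ebf1, the transcription factor of B cell commitment, differed by 1.38, Igll1 by 0.73 and Il7r by 0.70. Ebf1, Igll1 and Il7r had an unadjusted limma p above 0.05, while that of Ccr9 was 0.0082 and that of Rag1 0.032. The wild-type signal of Rag1, 2.93 with an SD of 0.48, lay close to background, so the size of its difference is uncertain. No member of either list passed over all genes or adjusted over the list alone. The brightest members of the B cell list, Cd79b and Ighm, differed by -0.05 (SE 0.23) and 0.47 (SE 0.55). List medians were 0.43 and 0.45 for lymphoid priming, and 0.81 and 0.63 for B cell genes, within the samples numbered 1 and 2. Both lists also went with the sample number, with medians higher in sample 2 than in sample 1 by 0.22 in wild type and 0.38 in Crebbp+/- for lymphoid priming, and by 0.30 and 0.48 for B cell genes. Without wild-type sample 1 neither list was called (medians 0.18 for lymphoid priming and 0.36 for B cell genes, adjusted p = 0.22 for each), and lymphoid priming was also lost without Crebbp+/- sample 2 (median 0.20, adjusted p = 0.28). With no filter neither was called (medians 0.06 and 0.03, adjusted p = 0.15 for each), and over the upper 25% of probe sets lymphoid priming was not (median 0.27, adjusted p = 0.24).

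Genes of stem cell identity were lower as a group. Of 38 stem cell genes 23 had a negative difference, with a median of -0.21 (camera adjusted p = 0.0015). The median of 15 Hox, Meis and Pbx genes was -0.27 (adjusted p = 0.019) and that of 8 megakaryocyte genes was -0.10 (adjusted p = 0.017). With an estimated correlation the adjusted p was 0.82 for each of the 3 lists. Stem cell and Hox lists share 7 genes, and stem cell and megakaryocyte lists share 2. Without shared genes none of the 3 was called, in tests chosen after seeing the data. The 27 stem cell genes outside the Hox, megakaryocyte and endothelial lists had a median of -0.12 (adjusted p = 0.090), the 8 Hox genes outside the stem cell list -0.02 (adjusted p = 0.52) and the 6 such megakaryocyte genes -0.10 (adjusted p = 0.12). Vwf, encoding von Willebrand factor, differed by -1.64 (SE 0.32) and Gp9, a platelet glycoprotein, by -1.21 (SE 0.31), and both passed adjusted over the megakaryocyte list alone (adjusted p = 0.033 and 0.0498), not over all genes. The Vwf signal of 2.77 in Crebbp+/- lay at background, so the size of its difference is uncertain. Meis1, a Hox cofactor, differed by -1.26 (SE 0.40), while Pbx3, another cofactor, differed by 0.66 (SE 0.21). Rab27b and Cd9, the brightest megakaryocyte genes, differed by 0.15 (SE 0.38) and -0.02 (SE 0.34). Stem cell medians were -0.23 and -0.03 within the samples numbered 1 and 2, Hox medians were -0.0045 and -0.16, and megakaryocyte medians were -0.26 and -0.10. From sample 1 to sample 2 the medians differed by -0.0037 in wild type and -0.043 in Crebbp+/- for stem cell genes, by 0.0044 and -0.15 for Hox genes and by -0.074 and -0.056 for megakaryocyte genes. Without wild-type sample 1 none of the 3 was called (medians -0.12, -0.23 and -0.18, adjusted p = 0.22, 0.35 and 0.22 for stem cell, Hox and megakaryocyte genes). Hox and megakaryocyte genes were also lost without Crebbp+/- sample 2 (medians -0.29 and -0.18, adjusted p = 0.28 and 0.084) and without array 1 of wild-type sample 2 (medians -0.18 and -0.02, adjusted p = 0.068 and 0.10). Hox genes were further lost without array 1 of Crebbp+/- sample 1 (adjusted p = 0.054), over the upper 25% of probe sets (0.056) and with the mean of a gene's probe sets (0.079). Megakaryocyte genes were lost with no filter (median -0.02, adjusted p = 0.15). With the sample number as a replicate block camera called neither Hox nor megakaryocyte genes (adjusted p = 0.062 for each). Calls that held had other medians. For stem cell genes it was -0.11 without Crebbp+/- sample 1 and -0.12 over the upper 25%, and for Hox genes -0.03 with no filter. For megakaryocyte genes it was -0.32 without wild-type sample 2, -0.17 without Crebbp+/- sample 1, -0.21 and -0.19 without array 2 of each of these samples, -0.19 with the mean of a gene's probe sets and -0.18 with the Gapdh covariate, a fit chosen after seeing the data.

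Targets of the transcription factor CREB, which recruits CBP, were lower as a group, as were immediate early genes. Of 16 CREB targets 13 had a negative difference, with a median of -0.27 (camera adjusted p = 0.019), and of 21 immediate early genes 17 did, with a median of -0.21 (adjusted p = 0.020). With an estimated correlation the adjusted p was 0.82 and 0.83. The lists share 6 genes, and immediate early genes respond to handling of cells. Without the shared genes, tests chosen after seeing the data called neither list, with medians of -0.12 over 10 CREB targets (adjusted p = 0.19) and -0.15 over 15 immediate early genes (adjusted p = 0.17). Sik1, encoding a salt-inducible kinase, differed by -1.44 (SE 0.59) and Gem, a small GTPase, by -0.46 (SE 0.25). Fosb and Klf4 differed by -0.71 (SE 0.60) and -0.39 (SE 0.34), and the brightest immediate early genes, Jund and Fos, by -0.21 (SE 0.21) and -0.29 (SE 0.38). No member passed. Immediate early genes also went with the sample number. Their medians were higher in sample 2 than in sample 1 by 0.58 in wild type and 0.77 in Crebbp+/-. Medians of CREB targets were higher by 0.42 and 0.64. Omitting a sample leaves the genotypes unequal in sample number, so these shifts then enter the difference between genotypes. Both calls were lost without wild-type sample 2 (medians -0.07 for CREB targets and 0.08 for immediate early genes, adjusted p = 0.50 and 0.91), without Crebbp+/- sample 1 (medians 0.02 and 0.20, adjusted p = 0.80 and 0.52), and with the Gapdh 5' minus 3' signal as a covariate, a fit chosen after seeing the data (medians -0.11 and 0.07, adjusted p = 0.32 and 0.81). Both kept their calls, with medians of -0.45 and -0.49, without wild-type sample 1, and with -0.66 and -0.62 without Crebbp+/- sample 2. Omitting array 2 of wild-type sample 1 ended the call of CREB targets (0.068), and omitting array 2 of wild-type sample 2 or of Crebbp+/- sample 1 that of immediate early genes (0.070 and 0.055). Within the samples numbered 1 and 2 the medians were -0.36 and -0.16 for CREB targets and -0.29 and -0.12 for immediate early genes. With the sample number as a replicate block, camera at its preset correlation called both lists. Its adjusted p was 0.0014 for CREB targets and 0.00028 for immediate early genes. At the preset correlation these values do not measure the spread between samples. Without the block, the estimated correlation between genes was 0.25 for CREB targets and 0.76 for immediate early genes. There fry called neither list (adjusted p = 0.84 and 0.90).

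**Figure D3:**
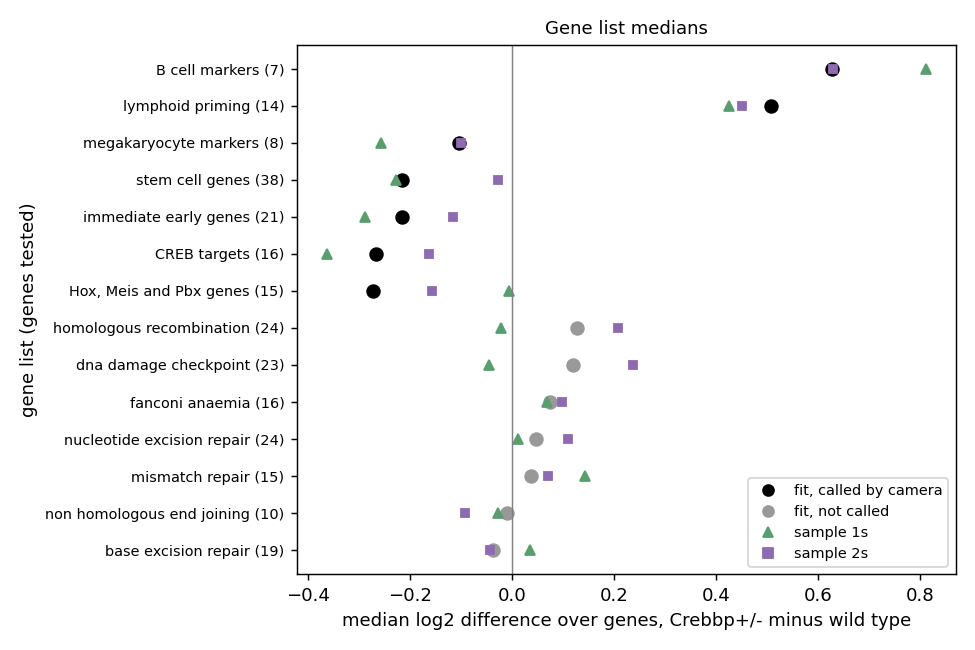
Median log2 difference over the genes of each list, Crebbp+/- minus wild type, for the 7 lists called by camera (black circles) and the 7 DNA repair and checkpoint lists (grey circles), with the number of genes tested in brackets. Triangles and squares give the medians within the samples numbered 1 and 2. The called lists run from -0.27 to 0.63 and the repair lists from -0.04 to 0.13.

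The other lists were not called, with a lowest camera adjusted p of 0.090 for endothelial genes (11 genes, median -0.27) and stromal genes (5 genes, median -0.21). Markers of other cell types that a fetal liver sort could hold differed unevenly. The hepatocyte median was 0.45 over 9 genes, with 1.49 within the samples numbered 1 and -0.85 within those numbered 2, and its camera statistic had the opposite sign. Fga and Dlk1 of that list differed by -1.08 (SE 0.72) and -0.36 (SE 0.23), with Fga at 2.34 in Crebbp+/-, below the filter. The erythroid median was 0.09 over 6 genes, with Slc4a1, the red cell anion exchanger, at 0.70 (SE 0.24) from a wild-type signal of 2.49, below the filter, and Gata1, the erythroid transcription factor, at -0.58 (SE 0.28). Macrophage genes had a median of -0.12 over 11 genes, with Lyz2 at -0.54 (SE 0.19), and T and natural killer cell genes 0.10 over 6 genes. Myeloid programme genes had a median of -0.10, with Cebpa at 0.47 (SE 0.33), and mitosis genes 0.13, with Kif11, a spindle motor, at 0.67 (SE 0.24). Genes mutated in myelodysplastic syndrome, among them Bcor at 0.48 (SE 0.30) and Idh1 at 0.29 (SE 0.20), had a median of 0.10. Acetyltransferase genes had a median of 0.07 and deacetylase genes -0.05. In lists too small to test, Cpa3 among mast cell genes passed adjusted over the list alone (adjusted p = 0.0026), while Mcpt8 and Kit differed by 0.20 (SE 0.22) and 0.12 (SE 0.21). Xist, the X inactivation transcript, differed by -0.33 (SE 0.12, limma adjusted p = 0.047 over the list alone, in which it was the only gene measured), and the Y-linked genes Eif2s3y, Uty and Kdm5d by -0.51 (SE 0.22), -0.95 (SE 0.52) and -0.16 (SE 0.27).

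Genes beside Crebbp did not pass the test. Crebbp lies near a chromosome end, and 33 tested genes lay among the 25 nearest on each side. None of them passed, and since none of 10550 other genes did either, the shares could not be compared at that threshold.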

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

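Among 108 groups of 4 arrays of the same genotype, 5 held an array whose gap to its nearest neighbour took up over 0.829 of the group's range, and chance gives about 1 in 20 such groups. The 4 arrays of a genotype are 2 pairs, so they are not independent. The B1 repeat control had a log2 signal of 10.04 on wild-type sample 1 array 1, against 10.43 to 10.47 on the other wild-type arrays. Afp was at 6.37 on Crebbp+/- sample 1 array 1, against 7.05 to 7.11. On Crebbp+/- sample 2 array 1, Shisa2 was at 9.12, against 8.82 to 8.85, and Gm20199 was at 5.39, against 4.16 to 4.35. The per-array median of Fanconi anaemia genes was 7.04 on wild-type sample 2 array 1, against 6.53 to 6.60. Of 14 control probe sets above the filter, 0 were higher in Crebbp+/- on every array and 3 were lower on every array, the B1 repeat and a pair for 18S ribosomal RNA.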

How the results depend on the processing

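The 2-level block on 8 arrays, the Gapdh covariate, lists without shared genes and the count of neighbours by unadjusted p were chosen after the data had been seen. The count of 0 probe sets and 0 genes between genotypes held under other filters, thresholds, added normalizations and variance models, with the sample as a random block, and without any sample or array (0 in all 12 omissions). With the 8 arrays as independent, 1 probe set and 0 genes passed. Only 2 pairs of samples share a number and the labels do not call it a batch, so whether the numbers pair the samples is not known. If they do, the main fit counts the shared difference between numbers as spread. Deviations of same-numbered samples correlated across probe sets at 0.55, and 2209 probe sets differed between numbers in the fit with the number as a replicate block, where 0 differed between genotypes (lowest adjusted p 0.11) and 3673 had an unadjusted p under 0.05, against 1089 without the block. A replicate block on 8 arrays gave 38 probe sets and 18 genes with 4 levels (3 higher and 35 lower), and 667 probe sets and 439 genes with 2 levels (340 higher and 327 lower). Both treat the arrays of a sample as independent, which makes p-values too small if they are not. Of 7 lists called, 5 were called with the replicate block on sample means, which lost Hox and megakaryocyte genes (adjusted p = 0.062 for each). On 8 arrays the block with 4 levels lost both (0.055 for each), and that with 2 levels Hox genes (0.0501). Over the upper 25% of probe sets 4 lists were called, 3 of them among the 7, and with an estimated correlation or with fry 0 were called. Omitting a sample or array gave 4 to 8 called lists. Stem cell genes and B cell genes were each called in 11 of 12 omissions, lymphoid priming in 10, megakaryocyte genes and CREB targets in 9, Hox genes and immediate early genes in 8. Where a sample is omitted, the lone sample of that genotype is assumed to vary like the other pair, and the genotypes are no longer balanced in sample number. Neighbours of Crebbp with an unadjusted p under 0.05 numbered 2 of 33, and 0 passed adjustment with 10, 25 or 50 genes per side, as 0 did elsewhere. Signals near background limit what low probe sets can show. A list's direction across alternatives was read from the sign of its median and, for the called lists, also from camera's direction, a rule settled after the values had been seen. The cause of the changes below was not tested.

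Of 3395 single-gene values under alternatives, 3292 kept direction and side of the threshold, 62 turned direction and 41 newly passed, all under the blocks on 8 arrays. With the Gapdh covariate the brightest Crebbp probe set was at -0.15 and the second at -0.42, Rab27b at -0.087, Csf1r at 0.34, Zbtb16 at -0.025, Tek at -0.054, Vim at 0.029, Fos at 0.0015 and Kdm5d at 0.00091. Medians were then 0.075 for immediate early, 0.082 for base excision repair and 0.10 for end joining genes. With quantile normalization the second Crebbp probe set was at -0.033, Prtn3 at -0.037 and mismatch repair at -0.012. Over the upper 25%, nucleotide excision repair was at -0.021, end joining at 0.10 and Fanconi genes at -0.014, and with no filter end joining was at 0.011. With the mean of all probe sets of a gene, base excision repair was at 0.051 and end joining at 0.078. Omissions gave ranges of -0.26 to 0.39 for the brightest Crebbp probe set and -0.56 to 0.58 for the second, with -0.62 to 0.20 for immediate early genes, -0.66 to 0.017 for CREB targets, -0.094 to 0.12 for base excision repair, -0.10 to 0.12 for nucleotide excision repair, -0.021 to 0.11 for mismatch repair and -0.069 to 0.16 for end joining. Among genes they ran from -0.16 to 0.21 for Prtn3, -0.34 to 0.31 for Cd9, -0.88 to 0.0030 for S100a8, -0.24 to 1.18 for Ighm and -0.45 to 0.57 for Id2. Fga ran from -2.16 to 0.0077, Rab27b from -0.29 to 0.60, Csf1r from -0.98 to 0.62, Kit from -0.037 to 0.28, Zbtb16 from -0.11 to 0.14 and Tek from -0.15 to 0.27. Vim ran from -0.31 to 0.067, Kdm5d from -0.36 to 0.041, Tfrc from -0.046 to 0.39, Fosb from -1.47 to 0.050 and Fos from -0.82 to 0.24. Bag3 ran from -0.13 to 1.48, Mpo from -0.042 to 0.13, Cd79b from -0.19 to 0.081, Cish from -0.010 to 1.08 and Mcpt8 from -0.032 to 0.44.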

Other observations

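The tests of sample number and of globin genes reported in this part were chosen after the result was seen. Several gene groups not described so far differed little. Ribosomal protein genes had a median difference of -0.03, with Rpl14 at 0.21 (SE 0.23) and Rps7 at -0.07 (SE 0.09), and oxidative phosphorylation genes -0.03, with Ndufb7 at -0.27 (SE 0.20) and Sdhb at -0.20 (SE 0.17). Sterol synthesis genes had a median of 0.12, with 17 of 19 higher, among them Msmo1 at 0.69 (SE 0.33) and Acaca at 0.46 (SE 0.29). Ribosome biogenesis genes had 0.10, with Utp15 at 0.39 (SE 0.16) and Rrp9 at 0.67 (SE 0.29), and DNA replication genes 0.08, with Orc2 at 0.46 (SE 0.18) and Cdc6 at 0.35 (SE 0.22). Interferon response genes had 0.12, with Ifi27 at 0.71 (SE 0.22) and Usp18 at 1.31 (SE 0.49), and inflammatory signalling genes -0.09, with Tlr4 at 0.92 (SE 0.26) and Nfkbiz at -0.54 (SE 0.20). None of these lists or genes passed.

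Signalling and metabolic groups gave the same picture. Among Wnt and Notch genes (median 0.11), Lef1 differed by 1.03 (SE 0.24) and Fzd6 by 1.00 (SE 0.41), and among transforming growth factor and bone morphogenetic protein genes (0.17) Acvr1 differed by 1.09 (SE 0.49) and Eng by -0.66 (SE 0.33). Cytokine signalling genes had a median of 0.10, with Cish at 0.54 (SE 0.30) and Sh2b3 at 0.33 (SE 0.20), and adhesion genes -0.05, with Selp at -0.66 (SE 0.27) and Esam at -0.62 (SE 0.27). Glycolysis genes had a median of 0.00, with Ldhb at -0.73 (SE 0.28) and Egln1 at 0.57 (SE 0.26), antioxidant genes 0.10, with Nqo1 at -0.90 (SE 0.38) and Sod2 at 0.43 (SE 0.23), and haem and iron genes 0.18, with Slc11a2 at 0.82 (SE 0.36). Apoptosis genes had 0.10, with Bcl2l2 at 1.02 (SE 0.49), cell cycle entry genes 0.02, with Cdk6 at 0.39 (SE 0.16) and Cdkn1c at -0.82 (SE 0.46), and genes of the CREB and ATF family 0.14, with Crem at 0.67 (SE 0.43) and Creb1 at 0.23 (SE 0.19). Unfolded protein response genes had 0.08, with Ppp1r15a at -0.48 (SE 0.33) and Ddit3 at -0.39 (SE 0.28), and heat shock genes -0.01, with Bag3 at 0.67 (SE 0.55) from a wild-type signal of 2.68, below the filter, and Hspd1 at 0.13 (SE 0.12). The camera statistic had the opposite sign to the median for glycolysis, heat shock, erythroid and unfolded protein response genes. Kat6a and Ncoa1 among acetyltransferases differed by 0.30 (SE 0.20) and 0.74 (SE 0.50), and Hdac4 and Hdac7 by 0.58 (SE 0.35) and -0.45 (SE 0.27). None of these passed over all genes or over their list alone.

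Further members of cell type lists, chosen for the lowest p or the highest mean, had the values below, and none of these genes passed over all genes or over its list alone. Tie1, Egfl7 and Tek of endothelium differed by -0.73 (SE 0.32), -0.34 (SE 0.16) and 0.06 (SE 0.23), and Postn, Alcam and Vim of stroma by -0.95 (SE 0.40), -0.39 (SE 0.31) and -0.12 (SE 0.19). Lyz1 and Csf1r of macrophages differed by -0.65 (SE 0.29) and -0.18 (SE 0.62), and S100a8, Elane and Prtn3 of neutrophils by -0.44 (SE 0.33), -0.29 (SE 0.25) and 0.02 (SE 0.20). Klrd1 and Prf1 differed by 0.39 (SE 0.23) and 0.62 (SE 0.41), Id2 and Zbtb16 by 0.06 (SE 0.40) and 0.02 (SE 0.27), Car2 and Tfrc by -0.38 (SE 0.26) and 0.17 (SE 0.20), Hnf4a by 0.09 (SE 0.19) and Csf3r by -0.35 (SE 0.27).

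Probe sets with no listed gene name were lower in Crebbp+/-, with a median difference of -0.24 and 69.6% below 0, against 0.04 and 43.5% for probe sets with 1 name. Setting each unnamed probe set against named ones of the same mean level left -0.29 within the samples numbered 1 and -0.18 within those numbered 2, which argues against signal level. From sample 1 to sample 2 the unnamed probe sets moved against named ones by -0.08 in wild type and 0.00015 in Crebbp+/-, which argues against RNA integrity as measured by Gapdh. Within 686 genes, the difference between genotypes at probe sets designed on expressed sequence tags minus that at the gene's RefSeq-designed probe sets had a median of -0.075 and -0.15 in the 2 sample numbers, so more unspliced or other non-mRNA template in wild type may contribute. An effect of genotype on such transcripts stays open and untested.

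Samples numbered 1 and 2 differed alike in both genotypes. The Gapdh 5' minus 3' signal was lower in sample 2 by -1.37 in wild type and -0.996 in Crebbp+/-, and the actin control by -1.05 and -0.66. The hepatocyte median in sample 2 minus that in sample 1 was 2.63 in wild type and 0.012 in Crebbp+/-, which argues against hepatocyte RNA for the shared part of the difference. With 1 sample of each number in a genotype, the spread of these controls between samples of the same number is unknown, so RNA integrity cannot be told apart from litter, day or sort, which are not in the labels.

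Globin probe sets did not move together, none passed adjustment, and of 5 tested 3 lay above the filter in both genotypes. Of the 3, a probe set that several adult beta-globin genes share differed by -1.70 (SE 0.22), while the bright alpha-globin probe set for Hba-a2 differed by 0.24 (SE 0.43) and that for Hbb-b2 by 0.01 (SE 0.25). The other 2, shared by the alpha-globin genes, had signals of 4.26 and 4.64 in Crebbp+/- and of 2.40 and 2.33 in wild type. Both were higher on every Crebbp+/- array, opposite to the beta-globin probe set. The wild-type signals lay below the filter, so these differences have no reliable size. The sort for lineage-negative cells should remove erythroid cells, and the erythroid list had a median of 0.09. With 1 of 3 probe sets lower, fewer erythroid cells in the gate of Crebbp+/- cannot be told apart from a strain difference in the probed sequence or an effect of genotype, since probe sequences were not used here.

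With 4 samples there are 3 splits into pairs, too few for a share under 0.05. For changed probe sets the real split gave 0 and the highest other split 0, so all 3 were as large, and for gene lists the real split gave 7 and the highest other 1, so 1 of 3 was as large. The split by sample number gave 4222 probe sets with an unadjusted p under 0.05, against 1089 for genotype and 154 for the crossed split, which points to a structure by sample number. A mutant allele carried on flanking DNA of another strain could shift signals of linked genes. Among genes nearest Crebbp, 2 of 33 had an unadjusted p under 0.05, or 6.06%, against 2.66% of other genes (Fisher's exact test p = 0.22, two-sided), which left this open.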
